A study of Mus musculus with 6 samples.

How the data were processed

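Diaphragm RNA was measured in 3 mdx and 3 mdx_PtencKO libraries by poly(A) RNA-seq. Per the labels and the series' design text, reads were paired-end Illumina reads cleared of adapters and low quality, mapped with TopHat2 to GRCm38/mm10 and counted per gene with HTSeq 0.6.1. The annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table with the read count of each gene in each library. Per the file headers it also holds a normalized signal, an FPKM value, gene length and coordinates, and the authors' comparison of the genotypes. The deposited normalized signal is the count divided by 1 factor per library (0.906, 0.855 and 1.17 for mdx replicates 1 to 3, and 0.952, 1.14 and 1.03 for mdx_PtencKO replicates 1 to 3); it was used only for that check. The deposited FPKM values divide by gene length and by a library total, which exceeds the sum of the counts by 26998, 27336 and 18843 reads in mdx replicates 1 to 3 and by 4128 reads in mdx_PtencKO replicate 3, and equals it in the other libraries. Those reads are outside the counts analysed here, and the genes they belong to were not determined. They came to at most 0.161% of a library.

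The authors' deposited table gives a log2 fold change, a p-value and an adjusted p-value for each gene, and per the labels DESeq2 or edgeR was used with adjusted p under 0.05. By those deposited columns 1291 genes differed, 103 higher and 1188 lower in mdx_PtencKO, and 3301 genes had no adjusted p. In the authors' deposited table Pten has a log2 fold change of -0.37 with an adjusted p of 0.0698, and Xist has no p-value. Of the 21375 gene identifiers, 21165 were found in GENCODE M21 for GRCm38, and 14380 had the same start and end there. Coordinates are those of the table. Symbols of 25 genes that a spreadsheet had turned into dates were restored through the identifier.

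Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values (TMM) normalization, filterByExpr, and the quasi-likelihood F test on genotype alone. P-values were adjusted by Benjamini-Hochberg over 15431 genes. CPM values use TMM library sizes. Means and SDs of CPM are over 3 libraries. Fold changes are mdx_PtencKO over mdx, and the SE is the log2 fold change divided by the root of F. For genes with few reads in mdx_PtencKO, the fold of pooled CPM is given with an exact (Clopper-Pearson) 95% counting interval. Shares of reads carry 95% Wilson intervals. Before the data were examined, 33 gene lists were fixed, and each had at least 5 measured members. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and by a one-sided Fisher's exact test among the genes that rose or fell.

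Named genes follow a rule fixed at the same time. It takes Pten, then the 10 largest rises and the 10 largest falls among genes that passed, with no overlap between genotypes, a mean of at least 2 CPM in the higher genotype and a symbol that is not a predicted-gene name. It then takes up to 4 members with the smallest p of each list that camera called or that held at least 3 passing members. The gene test and the list test were tried on simulated counts with 200 changed genes among 15217 tested for this comparison. Of 50 genes changed by each log2 size, 0 were recovered at 0.5, 19 at 1, 37 at 2 and 50 at 4, with 6 false calls. In simulated counts, camera called 0 of 33 unchanged lists, and when 1 list was shifted by -1 it called that list and 1 other. The simulated genes were drawn independently, so these counts cannot show how often camera wrongly calls lists of correlated genes.

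Libraries differed from each other by more than sampling noise in every pair, the closest pair by a chi-square of 25.2 per degree of freedom, so none was treated as a repeat. Correlations of log2 CPM across genes, which are not independent replicates, were 0.978 to 0.982 within mdx, 0.946 to 0.975 within mdx_PtencKO and 0.836 to 0.901 between genotypes. Alternatives fixed in advance were DESeq2 size factors in edgeR, total count only, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, a log2 fold change of at least 1, the replicate number as a block, each library left out in turn, camera with estimated correlation, fry, and the authors' adjusted p. After the data were seen, sex as a term, male libraries only, a fit without liver-list genes, a fit without genes of chromosomes X and Y, camera on ranks, scaling to contractile genes and total count without the fallen genes (library size taken as the reads of all genes but the 954 that fell) were added. Sex was read from Xist against the Y-linked genes Kdm5d and Uty. Also added were a wider list of hepatocyte genes and a list of markers of the other cells of the liver (Kupffer, sinusoidal endothelial, stellate and bile duct cells).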

Results

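Poly(A) RNA was sequenced from the diaphragm of 10-week-old mdx mice on the D2.B10 background. The mdx mouse lacks dystrophin and is a model of Duchenne muscular dystrophy. The libraries fall into 2 groups of 3, mdx mice and mdx mice in which Pten had been knocked out (mdx_PtencKO). Pten encodes a lipid phosphatase that opposes phosphoinositide 3-kinase signalling. Reads assigned to genes numbered 18697650, 16933065 and 23108503 in mdx replicates 1 to 3, and 19099544, 19974566 and 18979792 in mdx_PtencKO replicates 1 to 3. The table lists 21375 genes, of which 15431 had enough reads to be tested. The design implies 1 comparison, mdx_PtencKO against mdx, which asks how the loss of Pten changes transcript levels in dystrophic muscle. The labels call the libraries separate samples of a genotype without saying that each came from its own animal, so the p-values measure the spread between these libraries.

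Pten transcript, the target of the knockout, was lower in every mdx_PtencKO library than in any mdx library, but by a small margin. Pten (ENSMUSG00000013663) lies on chromosome 19, from 32757497 to 32826160 on the plus strand of GRCm38. Its level in CPM, reads scaled to library size, was 146, 152 and 138 in mdx replicates 1 to 3, and 106, 117 and 119 in mdx_PtencKO replicates 1 to 3. The means were 146 ± 6.95 (SD, n = 3) and 114 ± 7.18 (SD, n = 3), which is 21.8% lower in the knockout. The log2 fold change was -0.35 (SE 0.12) with an edgeR adjusted p of 0.182, so Pten did not pass the test. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The sources used here do not say which exons were removed or in which cells, so a count over the whole gene in whole tissue is a weak check of the labels.

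The mdx diaphragms carried abundant liver transcripts that were nearly gone from the mdx_PtencKO diaphragms, and these made up the largest differences in the data. All 14 measured genes of the liver list fell, with a median log2 fold change of -7.77, a 219-fold difference. The size of the fold rests on the liver reads left in mdx_PtencKO replicate 1, without which the median was -10.02. Alb, which encodes serum albumin, stood at 14366 ± 2219 CPM in mdx and 97.1 ± 131 CPM in mdx_PtencKO (SD, n = 3 each; log2 fold change -7.21, SE 1.37, edgeR adjusted p = 0.0199); it was picked out after its values were seen, and it did not pass without mdx replicate 1, mdx replicate 2 or mdx_PtencKO replicate 2. By the naming rule, the list's examples were Serpina1a, an antitrypsin gene, at -7.54 (SE 0.69), Ahsg, which encodes fetuin-A, at -7.16 (SE 0.76), and the apolipoprotein genes Apoa1 at -8.22 (SE 1.05) and Apoc3 at -7.42 (SE 1.02). The list took 3.23% of the reads in mdx replicate 1 (95% Wilson interval 3.23% to 3.24%), 3.45% in replicate 2 (3.44% to 3.45%) and 2.40% in replicate 3 (2.40% to 2.41%). In the mdx_PtencKO libraries it took 0.0406% (0.0397% to 0.0415%), 0.00718% (0.00682% to 0.00757%) and 0.00164% (0.00147% to 0.00184%). These intervals cover counting error only.

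**Figure D1:**
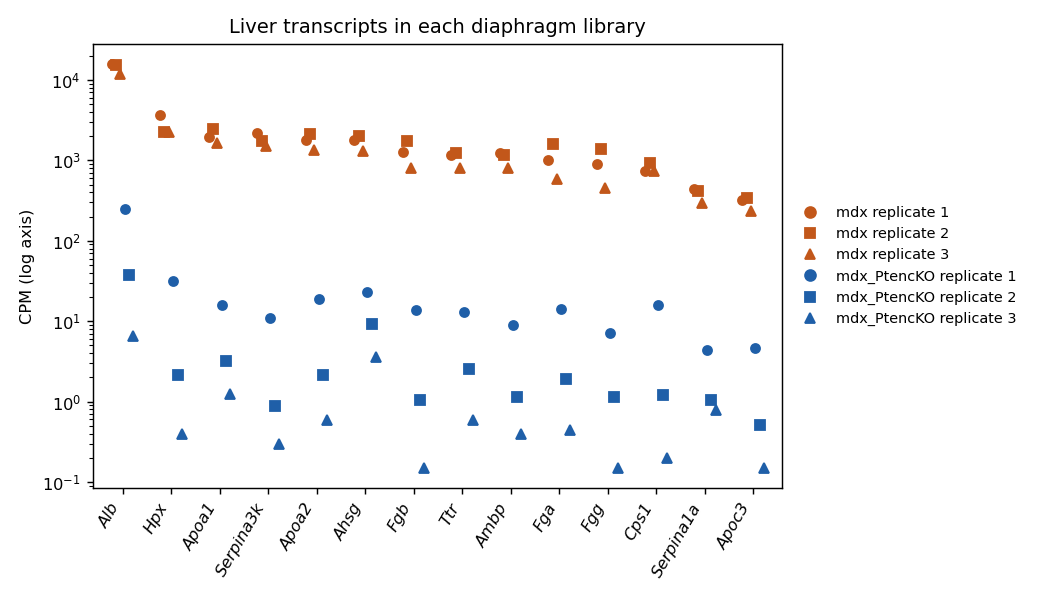
CPM (log axis) of the 14 measured genes of the liver list in each library, with genes ordered by their mdx mean. Each point is 1 library (orange, mdx; blue, mdx_PtencKO), and in every gene the 3 mdx libraries lie above the 3 mdx_PtencKO libraries.

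Of the genes that passed the test, most were lower in the knockout. 954 genes fell and 23 rose in mdx_PtencKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 the split was less uneven, with 1669 genes lower and 860 higher. It turned to 1359 lower and 1705 higher when libraries were scaled by total count only, and to 1946 lower and 40 higher with scaling to contractile genes. Of the genes that fell, 596 had a log2 fold change of -2 or lower, 225 lay between -2 and -1, and 133 above -1. The 10 largest falls among the named genes were all of genes known for expression in liver or kidney. They comprised the major urinary protein genes Mup3 and Mup9, the cytochrome P450 genes Cyp2d9, Cyp2a5 and Cyp2c67, Serpina1e, the organic anion transporter Slco1a1, the glucuronosyltransferase Ugt2b1, the serum amyloid gene Saa4, and Keg1. Cyp2d9 had 17970 reads in the mdx libraries together and 6 in the mdx_PtencKO libraries, a 3145-fold difference in pooled CPM (95% counting interval 1445 to 8572). The pooled folds of the 10 genes ran from 903 for Keg1 (309 to 4383) to 16677 for Serpina1e (5706 to 80873), each resting on 32 or fewer mdx_PtencKO reads. Serpina1e, Mup3, Mup9 and the P450 genes belong to families of near-identical copies, so their counts are uncertain. Serpina1e had 53 reads in mdx replicate 2 against 25260 and 22326 in the other mdx libraries, and its call was lost on leaving out mdx replicate 1 or any mdx_PtencKO library. The first principal component of the 500 most variable genes carried 94.6% of their variance and parted the genotypes. Of those 500 genes, 184 belong to the liver list or the wider hepatocyte list. The genotypes also differ in liver transcripts, so this component does not tell genotype from liver content.

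**Figure D2:**
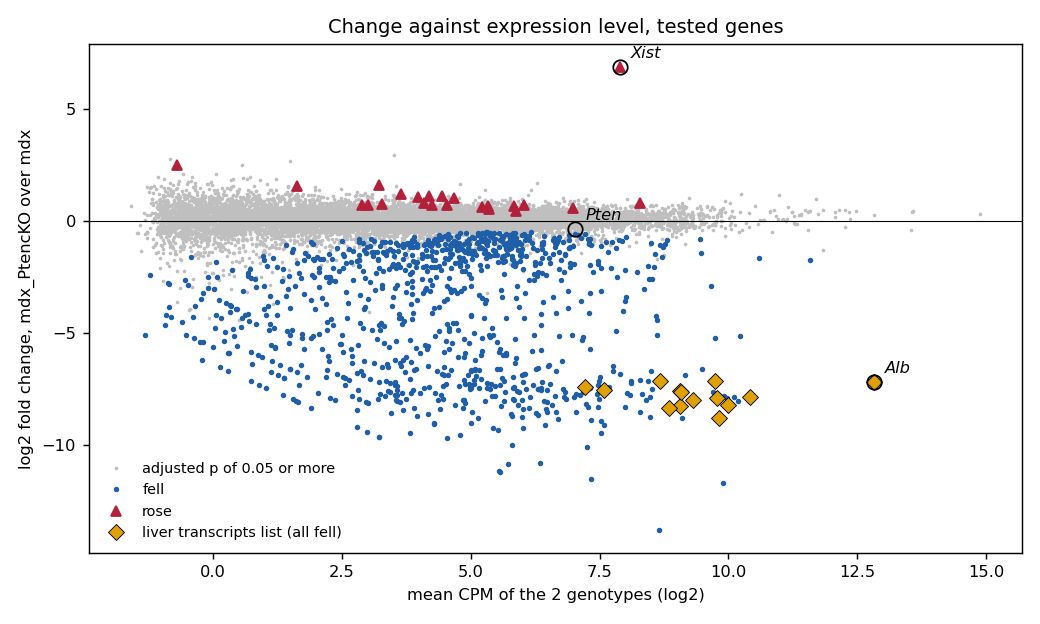
Log2 fold change of mdx_PtencKO over mdx for each tested gene against its mean CPM over both genotypes (log2). Grey points did not pass (adjusted p of 0.05 or more), blue points fell (954 genes with the liver list), red triangles rose (23 genes) and yellow diamonds are the 14 liver genes, which lie near the bottom of the plot.

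Genes of sterol synthesis fell together. Of 24 measured members, 16 fell, none rose, and the median log2 fold change was -1.34; with sex as a term 7 fell. Dhcr24, the reductase of the sterol side chain, fell from 157 ± 29.3 to 12.8 ± 2.97 CPM (SD, n = 3 each; log2 fold change -3.61, SE 0.23, edgeR adjusted p = 0.000129). Tm7sf2, a sterol reductase, changed by -3.03 (SE 0.19), Insig1, the feedback regulator of the pathway, by -2.64 (SE 0.28), and Ebp, a sterol isomerase, by -1.45 (SE 0.16). Not every member of the list fell. Hmgcs1, which makes the HMG-CoA that feeds the pathway, stood at 90.8 ± 27.6 and 92.6 ± 7.06 CPM, and Srebf2, its transcription factor, at 77.8 ± 6.29 and 77.5 ± 9.31 CPM (SD, n = 3 each). Neither gene was picked by the naming rule. The mdx libraries also held liver transcripts, so similar levels in both genotypes do not show that either gene was unaffected in muscle. The list had a camera adjusted p of 1.23e-16 with the preset correlation and an adjusted p = 0.943 with an estimated correlation. The latter setting called none of the 33 lists. Adjusted over the list alone 19 members of the sterol list fell. The count of 16 became 12, 13 and 17 without mdx replicates 1, 2 and 3. It was 16, 18 and 11 without mdx_PtencKO replicates 1, 2 and 3. Its share of fallen genes also exceeded that of all tested genes (16 against 1.48 expected; one-sided Fisher's exact test, adjusted p = 6.13e-13). The mdx libraries, higher in these genes, were also the libraries with liver transcripts, and the liver is a main site of sterol synthesis.

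Complement and acute phase genes fell as well, in 7 of 16 measured members with a median log2 fold change of -1.01. Orm1, an acute phase glycoprotein, changed by -7.09 (SE 0.59), Hp, which encodes haptoglobin, by -5.16 (SE 0.55), Cp, which encodes ceruloplasmin, by -1.96 (SE 0.29), and Lbp, which encodes the lipopolysaccharide-binding protein, by -0.92 (SE 0.16). Hepatocytes secrete the products of all 4 genes. The list's camera adjusted p was 1.37e-06, against an adjusted p = 0.943 with an estimated correlation and 0.0610 with fry. Its Fisher adjusted p for fallen genes was 0.000519 (7 against 0.989 expected), and adjusted over the list alone 11 members fell. The count of 7 became 3 without mdx replicate 1 or 2, 4 without mdx_PtencKO replicate 3, 3 with total count only and 2 with sex as a term; Lbp was among the losses without mdx replicates 1 and 2. The liver list had a camera adjusted p of 6.93e-16 and a Fisher adjusted p of 7.19e-16 (14 against 0.866 expected), and adjusted over the list alone all 14 fell; with an estimated correlation its adjusted p was also 0.943.

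Interferon-stimulated genes leaned lower in the mdx_PtencKO diaphragms, and few of them passed the gene test. Of 28 measured members 27 had a negative log2 fold change, with a median of -0.72, and 6 fell past the test. Iigp1, an immunity-related GTPase, fell from 172 ± 24.2 to 38.5 ± 8.07 CPM (SD, n = 3 each; log2 fold change -2.16, SE 0.19, edgeR adjusted p = 0.000486). Igtp, a related GTPase, changed by -1.17 (SE 0.12), Isg15, a ubiquitin-like modifier, by -1.47 (SE 0.25), and Rtp4 by -0.98 (SE 0.18); Ifit1 and Xaf1 were the other 2. The camera adjusted p was 2.75e-07, but the adjusted p = 0.943 with an estimated correlation and 0.0610 with fry, and the Fisher test did not pass (adjusted p = 0.106). Adjusted over the list alone 23 members fell. With sex as a term, an alternative chosen after seeing the data, the median was -0.38. The count of 6 became 3, 2 and 3 without mdx replicates 1, 2 and 3, 4 without mdx_PtencKO replicate 2 and 13 without mdx_PtencKO replicate 3. It was 3 with total count only and 10 with the replicate block. Isg15 lost its call without mdx replicate 2, and Rtp4 without any single mdx library. The mdx libraries, which were higher in these genes, were also the libraries with liver transcripts.

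Of the mesothelium markers, the keratins Krt18 and Krt8 fell, by -1.90 (SE 0.16) and -1.80 (SE 0.17) on the log2 scale. Both are keratins of simple epithelia and are also made by hepatocytes. Upk1b and Krt7 had log2 fold changes of -0.72 (SE 0.24, edgeR adjusted p = 0.173) and -0.74 (SE 0.25, edgeR adjusted p = 0.177), and the other 8 measured members did not pass either. The list's median was -0.32, its camera adjusted p 0.00526, and adjusted over the list alone 5 members fell. The call was lost with an estimated correlation (adjusted p = 0.943), with fry (0.0663), without mdx_PtencKO replicate 1 (0.173), with sex as a term (0.128, median -0.15), in male libraries only (0.253) and with scaling to contractile genes (0.0572). Without mdx_PtencKO replicate 3 it was stronger, with a median of -0.50, an adjusted p of 3.92e-05 and 5 members that fell over all genes.

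Among the genes that rose, the change was largest in Xist. This gene, the RNA that coats the inactive X chromosome, lies on chromosome X from 103460375 to 103483217. It had 13061 and 14713 reads in mdx_PtencKO replicates 1 and 2, 257 in mdx_PtencKO replicate 3, and 54, 93 and 75 in the mdx libraries (log2 fold change 6.89, SE 1.39, edgeR adjusted p = 0.0261). The Y-linked genes Kdm5d and Uty, looked up after seeing Xist, had 1 read or none each in mdx_PtencKO replicates 1 and 2 and 324 to 484 reads each in the other 4 libraries. The labels used here give no sex. How reads were assigned by strand is not stated, so reads of the antisense gene Tsix may be counted with Xist. The other 9 of the 10 largest rises among genes with a mean of at least 2 CPM in the higher genotype had folds from 1.73 to 3.10. Below that level Slc25a18, a mitochondrial carrier gene named after its values were seen, rose by 2.51 (SE 0.49, edgeR adjusted p = 0.0234), with 4, 4 and 2 reads in the mdx libraries and 24, 19 and 19 in the mdx_PtencKO libraries. Frem2, a basement membrane protein gene, went from 4.56 ± 0.680 to 14.1 ± 5.44 CPM and Adamts17, a secreted protease gene, from 1.54 ± 0.350 to 4.69 ± 0.496 CPM (SD, n = 3 each; log2 fold changes 1.63, SE 0.30, and 1.59, SE 0.27). Fbp2, the muscle fructose bisphosphatase, rose by 1.22 (SE 0.28), Cx3cl1, a chemokine, by 1.14 (SE 0.22), Prkg1, a cGMP-dependent kinase, by 1.12 (SE 0.25), and Tmem158 by 1.09 (SE 0.25). Aplnr, the apelin receptor, rose by 1.01 (SE 0.19), Rab15 by 0.83 (SE 0.19), and Col15a1, a basement membrane collagen, by 0.79 (SE 0.16).

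The number of rising genes was unstable. It was 4, 3 and 12 without mdx replicates 1, 2 and 3, and 41, 13 and 93 without mdx_PtencKO replicates 1, 2 and 3; of the 23 genes, 1, 1, 4, 12, 7 and 12 were called again. With the sex read from Xist and the Y-linked genes as a term, an alternative chosen after seeing the data, 0 genes rose at an adjusted p under 0.05 in edgeR (141 at an unadjusted p under 0.05) and 554 fell, while DESeq2 on genotype alone gave 118 rising genes. In the fit with sex, all 22 of the rising genes other than Xist kept a positive log2 fold change, from 0.40 to 2.36, with a median of 0.65 against 0.75, while their median SE went from 0.16 to 0.22.

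**Figure D3:**
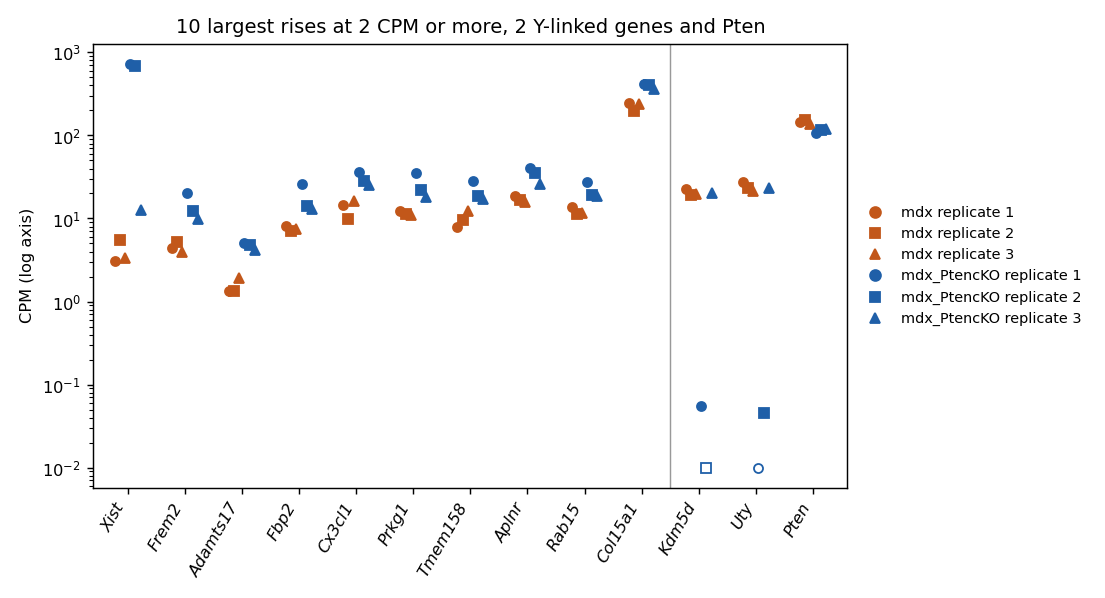
CPM (log axis) in each library of the 10 genes with the largest rise among those with a mean of at least 2 CPM in the higher genotype, of the Y-linked genes Kdm5d and Uty, and of Pten. Each point is 1 library (orange, mdx; blue, mdx_PtencKO), and open points drawn at 0.01 CPM are libraries with 0 reads. The rising genes were chosen to have no overlap between genotypes, so the mdx_PtencKO libraries lie above the mdx libraries in each of them. In 2 mdx_PtencKO libraries there was at most 1 read of each Y-linked gene.

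Endothelial markers were the only list called upward by camera with the preset correlation, at an adjusted p of 0.0214, against an adjusted p = 0.943 with an estimated correlation. All 18 members had a positive log2 fold change with a median of 0.32, and 1 member passed the gene test, over all genes and also adjusted over the list alone. That gene was Sox18, an endothelial transcription factor, at 0.67 (SE 0.13, edgeR adjusted p = 0.0244), and it did not pass without mdx replicate 1 or 2 or mdx_PtencKO replicate 1 or 3. Cdh5, the endothelial cadherin, stood at 0.55 (SE 0.21, edgeR adjusted p = 0.254), Egfl7 at 0.42 (SE 0.16, edgeR adjusted p = 0.263) and Pecam1 at 0.37 (SE 0.15, edgeR adjusted p = 0.291). The list's call was lost without mdx replicate 1 (adjusted p = 0.0594), without mdx_PtencKO replicate 1 (0.173), with sex as a term (0.114, median 0.18), in male libraries only (0.118), with scaling to contractile genes (0.101) and with fry (0.205). Scaling to contractile genes, chosen after seeing the data, lowers the median of all genes by 0.35, and the endothelial median became -0.06. Adding that shift back gives 0.29, which undoes the scaling and does not show that the rise outlasts it.

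Over the alternatives tried, the adjusted p ran from 6.23e-23 to 0.943 for sterol synthesis, 1.07e-116 to 0.943 for liver, 4.46e-13 to 0.943 for interferon, 3.84e-09 to 0.943 for complement and acute phase, 3.92e-05 to 0.943 for mesothelium and 2.63e-05 to 0.943 for endothelial markers. The 0.943 in each range came from camera with an estimated correlation. That setting called none of the 33 lists, the liver list included, so it does not tell the lists apart. Fry, which tests each list on its own, called liver (adjusted p = 0.0158) and sterol synthesis (adjusted p = 0.0447) and not the other 4. Of the 10 ways to split the 6 libraries 3 against 3, 9 gave at least 6 called lists with the preset correlation. The number of called lists was 11 without mdx replicate 3 and 13 without mdx_PtencKO replicate 2.

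Lists of the muscle fibre and its metabolism were not called. Median log2 fold changes were 0.51 for fast fibre genes, 0.26 for slow fibre genes, 0.39 for developmental and regenerating fibre genes, 0.33 for neuromuscular junction and denervation genes, 0.25 for the dystrophin-associated complex and 0.26 for myogenic progenitor and fusion genes. They were 0.34 for glycolysis and glycogen, 0.30 for the citrate cycle, 0.17 for oxidative phosphorylation, 0.19 for fatty acid oxidation and uptake and 0.33 for mitochondrially encoded genes. Mitochondrially encoded genes took 10.3% of the reads in mdx_PtencKO replicate 1 and 5.30% to 6.39% in the other 5 libraries. The smallest camera adjusted p among these lists was 0.0930, and single libraries decided much of their change. Without mdx_PtencKO replicate 1 their medians lay between -0.20 (fatty acid oxidation and uptake) and 0.11 (fast fibre). Without mdx_PtencKO replicate 2, 7 of these lists were called upward, among them fast fibre (median 0.74, adjusted p = 0.000674), oxidative phosphorylation (0.31, 0.00311) and glycolysis (0.49, 0.00362), while the slow fibre median turned to -0.06. Developmental fibre genes were also called without mdx replicate 1 (adjusted p = 0.0177) and, with fast fibre and junction genes, without mdx replicate 3 (0.0360, 0.0406 and 0.0441). The developmental list was called with the replicate block (0.0448), and fast fibre genes in male libraries only (0.0195) and with scaling to contractile genes (0.0378). With sex as a term the medians of slow fibre (-0.24), fatty acid oxidation and uptake (-0.08) and mitochondrially encoded genes (-0.05) turned negative. Those of the remaining fibre and metabolism lists stayed positive. Camera on ranks called 9 of these 11 lists. Members that fell on their own were Pcx, which encodes pyruvate carboxylase (-1.87, SE 0.17), Ppara, a fatty acid receptor (-1.61, SE 0.29), Sdc4, a syndecan (-1.54, SE 0.21), and Sntb1, a syntrophin (-1.07, SE 0.15); Ppara did not pass without mdx replicate 1 or mdx_PtencKO replicate 3. These members were higher in the mdx libraries, which also held the liver transcripts, so their fall cannot be assigned to muscle fibres. Fbp2, above, was the member that rose.

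The FoxO target and atrophy list, which holds genes controlled through the pathway that Pten restrains, had a median log2 fold change of 0.01 over 27 members and a camera adjusted p of 0.991. Klf15, a metabolic transcription factor, and Mt1, a metallothionein, fell by 1.21 (SE 0.25) and 1.18 (SE 0.27) on the log2 scale. Neither passed without mdx replicate 1, 2 or 3 or without mdx_PtencKO replicate 1, and Mt1 did not without mdx_PtencKO replicate 2. Both were higher in the libraries that held liver transcripts. The ubiquitin ligase genes of muscle atrophy did not pass: Fbxo32 stood at 114 ± 16.4 and 155 ± 33.5 CPM and Trim63 at 107 ± 36.8 and 140 ± 67.0 CPM (SD, n = 3 each). The medians of autophagy and lysosome genes (-0.06, 28 members) and of ATF4 and amino acid supply genes (0.03, 24 members) lay near 0, and no member of either passed.

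Markers of the remaining cell types and states were not called as lists. Medians were 0.27 for macrophage and monocyte markers, -0.14 for lymphocyte markers, -0.42 for neutrophil markers, 0.00157 for inflammatory cytokines and chemokines and 0.07 for proliferation genes. They were 0.22 for collagen and matrix, 0.05 for fibro-adipogenic progenitor markers, -0.36 for adipocyte markers, 0.32 for pericyte and smooth muscle markers, 0.24 for Schwann cell and nerve markers and 0.33 for tendon markers. Red blood cell transcripts had a median of -0.58 and immediate early and handling genes 0.38. Several of these values turned on 1 library. The adipocyte median was -0.76 without mdx replicate 3 and -0.28 without mdx_PtencKO replicate 1, and camera on ranks called that list downward (adjusted p = 0.000626). The macrophage median was 0.64 and called upward without mdx_PtencKO replicate 1 (adjusted p = 0.00294) and -0.28 without mdx_PtencKO replicate 2, and those of lymphocyte markers (0.15) and cytokines (0.22) were positive without mdx_PtencKO replicate 1. Collagen and matrix genes were called upward without mdx_PtencKO replicate 1 (0.29, adjusted p = 0.0193) and without mdx replicate 3 (0.19, 0.0438), and immediate early genes without mdx replicate 3 (0.39, 0.0406). Without mdx_PtencKO replicate 2 the medians of Schwann cell (-0.05), tendon (-0.02) and fibro-adipogenic (-0.02) markers turned negative, the last also without mdx replicate 3 (-0.02), and that of neutrophil markers was 0.07 without mdx replicate 1. With sex as a term, proliferation genes (0.58, adjusted p = 6.02e-06) and collagen and matrix genes (0.33, adjusted p = 0.00162) were called upward and red blood cell transcripts downward (-2.32, adjusted p = 0.0199); proliferation stood at -0.25 without mdx_PtencKO replicate 3. Single members that fell were Lcn2, a neutrophil lipocalin (-2.30, SE 0.27), Cxcl1, a chemokine (-2.16, SE 0.45), Alas2, of haem synthesis (-2.02, SE 0.24), Car3, a carbonic anhydrase (-1.43, SE 0.23), Cd163, a haemoglobin scavenger receptor of macrophages (-1.31, SE 0.25), and Dpp4, a peptidase (-1.17, SE 0.14). They too were higher in the libraries that held liver transcripts, so their fall cannot be assigned to the cell type of their list. Cspg4, a pericyte proteoglycan (0.65, SE 0.11), Tgfb2 (0.73, SE 0.17), Loxl2 (0.73, SE 0.13) and Col15a1 were the members that rose. Tgfb2 did not pass once any single library was left out, Loxl2 did not pass without mdx replicate 2 or 3 or mdx_PtencKO replicate 2, and Cspg4 not without mdx replicate 1 or 2. Of those that fell, Cd163 was lost without any single mdx library or mdx_PtencKO replicate 2, Cxcl1 without mdx replicate 1 or mdx_PtencKO replicate 1 or 3, and Car3 without mdx replicate 1. The members in this paragraph and in the lists of the fibre and its metabolism were chosen after their values were seen.

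**Figure D4:**
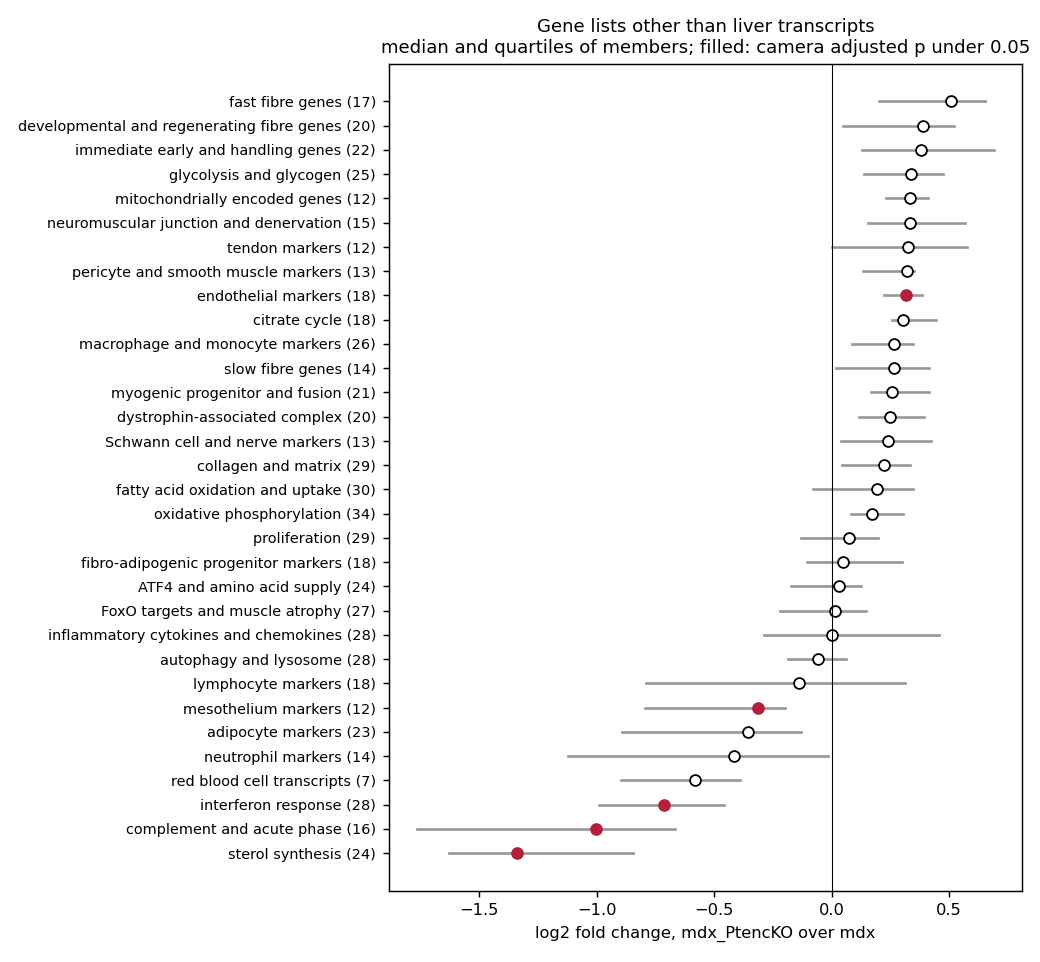
Median (point) and quartiles (grey line) of the log2 fold change of mdx_PtencKO over mdx in each gene list other than the liver list, whose median of -7.77 lies off this scale. Measured members are in brackets and filled points mark camera adjusted p under 0.05. Sterol synthesis lies lowest at -1.34 and fast fibre genes highest at 0.51.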

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

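Sex as a term, male libraries only, the fits without liver-list or sex chromosome genes, camera on ranks, scaling to contractile genes and scaling to the reads outside the fallen genes were chosen after seeing the data. The fall of 954 genes was the stable result: leaving out 1 library gave 740 to 1031 fallen genes (735 to 914 of them among the 954), and over the 21 alternatives that give a count it lay outside 1.5 times the reported value only with sex as a term, where 554 genes fell and 554 changed in all (547 shared). That fit compares mdx_PtencKO replicate 3 with the mdx libraries, which leaves fewer samples. Pten kept its direction and stayed short of the threshold under all 20 alternatives, with log2 fold changes of -0.69 to -0.26 and adjusted p of 0.0621 to 0.932. The 23 rising genes became 54 with total count only, 15 with no filter, 9 with a log2 fold change of at least 1, 118 with DESeq2, 15 with limma-voom, 103 by the authors' adjusted p, and 3 to 93 on leaving out 1 library. The number of rising genes became 0 with sex as a term, 15 without liver-list genes, 15 with total count without the fallen genes and 1 with scaling to contractile genes. These are counts, and the genes called were not always among the 23. The cause of these shifts was not tested. In the fit of male libraries only, 1 mdx_PtencKO library is assumed to vary like the mdx libraries, so no count of rising genes is given for it.

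Leaving out 1 library gave 6 to 13 called lists against 6, with 11 without mdx replicate 3 and 13 without mdx_PtencKO replicate 2. The number became 0 with an estimated correlation, 2 with fry and 21 with camera on ranks. The first principal component carried 85.9% of the variance without liver-list genes, against 94.6%. Fallen genes outside the liver list and the wider hepatocyte list (750 in the main test) were not removed in that setting. Scaling to contractile genes moved the median of all genes by -0.35, since these genes had a median log2 fold change of 0.33. That takes the endothelial list (median -0.0603) and Pecam1 (-0.0033) below 0, and the list's camera call was lost (adjusted p = 0.101). Adding the shift back gives 0.29 and 0.34, which only undoes the scaling. Of 39 named genes that passed, the 28 that fell lost at most 3 calls when 1 library was left out, and the 11 that rose lost 3 to 11.

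Whether the replicate numbers pair the libraries could not be told with 3 libraries per genotype. Deviations from the group means correlated at 0.04, 0.27 and 0.12 for numbers 1, 2 and 3. Between unlike numbers the correlations ran from -0.31 to 0.16, and not every library correlated best with its own number. A fit with the replicate block gave 968 changed genes, 18 risen and 950 fallen, and 7 called lists. Alternatives planned for a table without counts were not run, since counts were deposited. Depth and the spread between libraries limit the smallest changes: in the simulated counts none of 50 genes changed by 0.5 on the log2 scale was recovered.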

Other observations

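The tests on liver non-parenchymal markers, on the interferon list with sex as a term and on other splits of the libraries were fixed before their results were seen; all other tests here were chosen afterwards.

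Beyond the fixed liver list, 190 of 194 tested genes of a wider hepatocyte list fell, with a median log2 fold change of -7.22; this list was written after the main results were seen. Both lists together took 8.64%, 8.87% and 6.33% of the reads in mdx replicates 1 to 3 and 0.2004%, 0.159% and 0.144% in mdx_PtencKO replicates 1 to 3, where the widest 95% Wilson interval, that of mdx replicate 2, ran from 8.86% to 8.88%. Some markers of other liver cells were lower too. Of 20 tested, 8 fell, among them Clec4f of Kupffer cells (12.9 ± 5.12 against 0.0553 ± 0.0958 CPM), Clec4g of sinusoidal endothelium (11.8 ± 2.25 against 0.0738 ± 0.128 CPM) and Lrat of stellate cells (1.67 ± 0.555 against 0.208 ± 0.156 CPM; SD, n = 3 each). In every mdx_PtencKO library, 11 of these 20 markers, 3 of the 14 genes of the fixed liver list and 53 of the wider list stood at 1 CPM or more.

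In a fit with sex as a term, in which mdx_PtencKO replicate 3 stands against the mdx libraries, the liver list had a median of -11.28 and no member above -8.89, and 13 of 14 members passed, which argues against sex as the cause of the loss of liver transcripts. If muscle cells had expressed hepatocyte genes under the control of Pten, markers of other liver cells would have stayed, but 8 of them fell, more than the 5 set as the bound. Liver tissue RNA in the mdx libraries is a candidate explanation that stays open. The median of the non-parenchymal markers was -1.56, between the bounds of -2 and -1 set for and against it. This median is a weak guide, since 11 of the 20 markers stood at 1 CPM or more in every mdx_PtencKO library. Of the fallen genes, 750 lie outside both liver lists, and in mdx replicate 3, the mdx library with the fewest liver transcripts, these were lower than in the other mdx libraries by 0.38 on the log2 scale more than genes that did not pass (difference -0.38), which is consistent with liver RNA as a source of many of them. The same difference was -0.39 for the mean of the sterol list. The contrast sets 1 library against 2 and has no spread between libraries. Genotype and the level of liver transcripts are confounded in these libraries.

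The interferon list had a negative median in each of the 20 alternatives (-1.05 to -0.38), and its source is open. Among these, camera with estimated correlation, fry and camera on ranks reuse the main fold changes. Their median of -0.72 is therefore the main one and adds nothing on its sign. If liver RNA had carried it, mdx replicate 3 would have been lower than the other mdx libraries, but the list was 0.0468 higher there relative to genes that did not pass (SE 0.0344 over its genes, with no spread between libraries), too close to 0 to decide. With sex as a term the median was -0.38 with 26 of 28 members below 0 and a camera adjusted p of 0.00129 (4.46e-13 to 0.943 over the alternatives), between the bounds of -0.2 and -0.5. Sex rests on 1 male mdx_PtencKO library, so it cannot be told apart from genotype here. An effect of Pten on interferon signalling is a hypothesis that no test here separated from these.

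By CPM over all reads, Xist was 50.5 times higher in the lowest of the 2 libraries with at most 1 read of each Y-linked gene than in the highest of the others, which is consistent with mdx_PtencKO replicates 1 and 2 coming from females and the other 4 libraries from males. The other 22 rising genes had a median of 0.65 with sex as a term, against 0.75 without it, and none was below 0.2. None passed in that fit, in which the median SE grew from 0.16 to 0.22 as 1 male mdx_PtencKO library carried the comparison. That library also took part in the test that chose the genes, so sex cannot be told apart from genotype for them.

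Dilution of muscle RNA by liver RNA in the mdx libraries would lift every other transcript in the knockout. With total-count scaling the lift would be 0.12 on the log2 scale if liver RNA made up the reads of both liver lists. It would be 0.19 if liver RNA made up those of all fallen genes (11.2% to 15.3% of the mdx reads). The reported folds use TMM, under which the median of all genes was 0.05, against 0.14 with total count only, so they carry less of this lift. With libraries scaled to the reads outside the fallen genes, the 22 rising genes had a median of 0.65 (at least 0.63 with any library left out) and 14 of them passed. The endothelial median was 0.21 (at least 0.14 with any library left out), beside 0.24 for contractile genes (0.09 to 0.44) and -0.04 for fibro-adipogenic markers. The 22 genes exceeded the contractile genes in each of these fits by at least 0.19. They were chosen for their rise in the same libraries, so this excess cannot decide on dilution. Liver transcripts that did not fall are not in that share, and after scaling to contractile genes none of the 22 passed (median 0.41, median SE 0.27). With sex as a term the endothelial median was 0.18 (adjusted p 0.114; 2.63e-05 to 0.943 over the alternatives), so for that list, which did not exceed the contractile genes over the 6 libraries, dilution and sex both stay open, and an effect of Pten on vessels was not tested apart from them.

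Of the 10 splits of the 6 libraries 3 against 3, 1 gave as many changed genes as the genotypes, which was the real split with 977, and the highest other gave 0. As many called lists came from 9 of the 10 splits, with 6 in the real split and 22 in the highest other. With 10 splits no share can fall under 0.05. A count of called lists of this size is therefore not particular to the genotype split. Each other split still divides the genotypes unevenly, and what its list calls reflect was not tested.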
